A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

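DNA from 3 ChEC samples (uncleaved, H2b-MN and Nup2-MN) was labelled with biotin and hybridised to Affymetrix tiling arrays of yeast chromosome VI, per the labels' protocols and the README deposited with the data. Per that README, the authors grouped the array probes into probe sets of at most 16 probes, none of which spans a site of the restriction enzyme MboI. The deposited log2 values were computed by the authors with the robust multi-array average (RMA) in Bioconductor 1.5, per the README, and each is the mean of 3 independent experiments. RMA combines background correction, quantile normalization across arrays and a robust summary over the probes of a set. Quantile normalization makes arrays alike in distribution, so a shift common to most of the chromosome would be removed before any difference was taken. In each of the 3 columns 100.0% of the values became whole at the sixth decimal when multiplied by 3 (tolerance 0.05 of that decimal), as means of 3 values would. Values stored to no more than the sixth decimal would do the same, so this alone does not show averaging. The table of means used here holds no SDs and the individual arrays were not used here. The experiments are described as done on different days, but no day can be followed in the means.

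Samples were grouped by their descriptions, with 1 column each. Differences of log2 values were taken for Nup2-MN minus uncleaved, H2b-MN minus uncleaved and Nup2-MN minus H2b-MN, with no further normalization, filter or pseudocount. With 1 value per group no test between groups was made. A probe set was counted as higher or lower at a log2 difference of 1 (2-fold) or more. The number of arrays limits the precision, and the SDs given are over probe sets. Correlations across probe sets and between neighbours were given 95% intervals from 1000 circular block bootstraps in blocks of 25, which describe the variation along the chromosome and not between experiments. The part of the correlation that comes from the level of the shared uncleaved column was estimated from 100 permutations of the cleaved values within 20 bins of the uncleaved value. These do not keep the full measurement error of the uncleaved value that both differences share at a probe set. Runs, windows of 50 probe sets and correlations between neighbours were set against 1000 shuffled orders. They take the number in a probe set's identifier as its order, which no source used here states. The run length, the windows, the block bootstrap and the shuffles were chosen after the data were seen.

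The rule for named items, the 2-fold threshold, the 3 comparisons, the correlation of the profiles with its permutations, the correlations between neighbours and all alternatives except the one marked below as added were fixed before the data were examined. Where identifiers could not be tied to genes, the rule allowed the 2 highest and 2 lowest probe sets of each comparison. Of the 1250 identifiers, 0 matched an entry of the gene table at hand, and no genome was used, so values by promoter, coding region, gene list or distance from a chromosome end were not made. All stretches described outside the rule, including the longest runs and the first 10 probe sets, were picked after their values were seen. Alternatives were centring each column on its median, quantile normalization of the 3 columns, leaving out the lowest 10% of probe sets by mean signal, removal of a lowess trend with signal level (span 0.4), a 1.5-fold threshold, averaging over 3 neighbouring probe sets and, added later, leaving out the first and last 50 probe sets. The scripts were tested on simulated data: of 200 of the 1250 probe sets raised by 1.5 on the log2 scale in a simulated Nup2-MN minus uncleaved comparison, 100.0% passed the 2-fold threshold, and 0 of the others did. The simulated noise was small beside that step and independent between probe sets. The outcome checks the scripts and does not give the accuracy of the threshold in these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.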

Results

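The data describe chromosome VI of the budding yeast Saccharomyces cerevisiae, read on a tiling array after chromatin endogenous cleavage (ChEC). In ChEC, a protein of interest is fused to micrococcal nuclease (MN), a calcium-dependent enzyme that cuts DNA, and the fusion cuts the genome near the places where the protein sits in the living cell. Signal was given for 1250 probe sets in 3 samples: uncleaved DNA, DNA cleaved by a fusion of histone H2b (a core histone, present along most of the genome), and DNA cleaved by a fusion of Nup2 (a nucleoporin, a protein of the nuclear pore complex). Cells were grown on 2% raffinose and given 2% galactose for 1 h. H2b-MN cleaved for 1 min on ice and Nup2-MN for 5 min at 30 °C, so the 2 cleaved samples differed in time and temperature as well as in the fusion. Each deposited value was the mean log2 signal of 3 independent experiments, and their spread was not analysed here, so each group had 1 value per probe set. No difference below could be set against the error between experiments, and none carries a p-value. Probe sets are given by the identifiers of the deposited table, whose numbers run from 1 to 1250. Their coordinates and genes were not analysed here, and the direction in which cleavage moves the signal was not given in the sources used here.

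The 3 columns were on nearly the same scale. The median log2 signal was 7.57 in uncleaved DNA, 7.58 in H2b-MN and 7.42 in Nup2-MN, with SDs over the 1250 probe sets of 1.31, 1.32 and 1.36. Across probe sets, which are not independent replicates, uncleaved DNA correlated with H2b-MN at Pearson's r = 0.928 and with Nup2-MN at r = 0.892, and the cleaved samples correlated with each other at r = 0.927. The first 10 probe sets had a mean signal of 10.28 in uncleaved DNA, 10.22 in H2b-MN and 10.15 in Nup2-MN. The last probe set, c6Mbo1250, read 11.19, 10.36 and 10.94 in the same order.

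The first comparison asked where along chromosome VI Nup2-MN cleavage set the DNA apart from uncleaved DNA. Of the 1250 probe sets, 85 (6.80%) were at least 2-fold higher in Nup2-MN and 23 (1.84%) at least 2-fold lower. The highest was c6Mbo0830, at 10.18 against 7.76 in uncleaved DNA, a log2 difference of 2.41 (5.33-fold). It was followed by c6Mbo1215, at 9.58 against 7.30 (log2 difference 2.28). The lowest were c6Mbo0239, at 6.82 against 8.34 (log2 difference -1.52), and c6Mbo0420, at 6.62 against 8.08 (-1.46). High probe sets lay in groups of neighbouring numbers. Probe sets 422 to 426, picked after their values were seen, were all higher in Nup2-MN, by 1.37 to 2.03 on the log2 scale with a mean of 1.55, while the 5 probe sets before them, 417 to 421, were all lower, with a mean of -1.06. Probe sets 665 to 673, also picked after their values were seen, were higher by a mean of 1.34, with values from 0.42 to 2.09. The differences were skewed toward high values (skewness 0.73), although 40.9% of them were above 0 and their median was -0.15. Of the 108 probe sets past the threshold, 78.7% were higher, and this share was 93.9% (124 higher, 8 lower) once each column was centred on its own median and 88.1% (96 higher, 13 lower) with quantile normalization of the 3 columns. At a 1.5-fold threshold without centring the balance turned, with 212 probe sets higher and 287 lower. The SD of the difference over probe sets was 0.623.

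**Figure D1:**
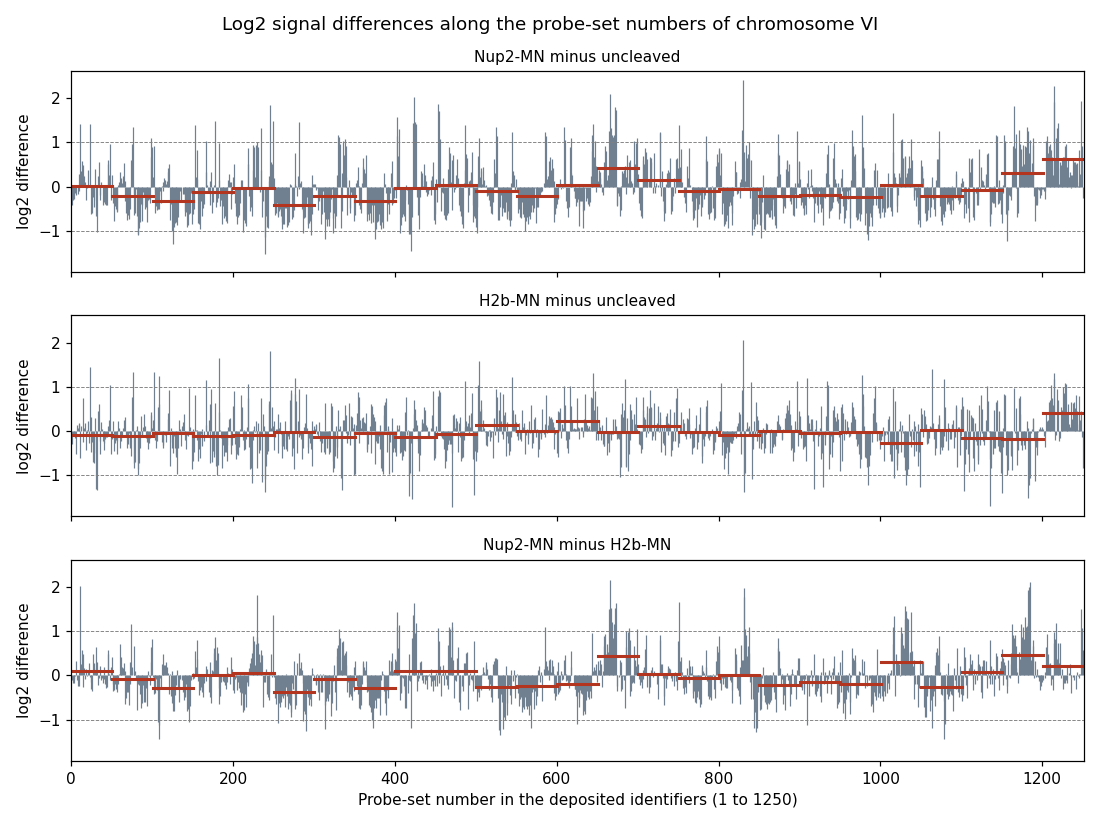
Log2 difference of each of the 1250 probe sets (vertical lines) against the probe-set number, for Nup2-MN minus uncleaved, H2b-MN minus uncleaved and Nup2-MN minus H2b-MN. Red bars are means over 25 windows of 50 probe sets and dashed lines mark 2-fold differences; the last window lies at 0.62 in the top panel and 0.41 in the middle one, above all other windows in those panels.

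The second comparison gave the same measurement for H2b-MN. Here 35 probe sets (2.80%) were at least 2-fold higher than in uncleaved DNA and 30 (2.40%) at least 2-fold lower, with a median of -0.04 and a skewness of 0.14. The highest was again c6Mbo0830, at 9.83 against 7.76 (log2 difference 2.07), followed by c6Mbo0246, at 8.45 against 6.65 (1.80). The lowest were c6Mbo0471, at 5.79 against 7.51 (-1.73), and c6Mbo1135, at 5.93 against 7.62 (-1.69). The SD of the difference over probe sets was 0.499. Probe sets 417 to 421 were lower in H2b-MN too, by a mean of -1.04, but 422 to 426 were higher by a mean of only 0.38 and 665 to 673 had a mean of 0.00.

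Across probe sets, the 2 cleavage profiles correlated at Pearson's r = 0.598 (95% block bootstrap interval 0.526 to 0.667, in blocks of 25 neighbouring probe sets) and Spearman's rho = 0.611. Both differences contain the same uncleaved values, which alone adds to the correlation. When the cleaved values were permuted among probe sets of similar uncleaved signal, 100 permutations gave a mean r of 0.076 and at most 0.146. The covariance was 0.186 against 0.026 in the permutations, a difference of 0.160. The shared uncleaved column could not be split, since it is a single mean, so part or all of the excess may lie in its measurement error. The permutations cannot show how much, since they do not keep that error at a probe set. The same limit holds for the overlaps and signs below. Of the 85 probe sets higher in Nup2-MN and the 35 higher in H2b-MN, 14 were the same, against 2.38 for independent lists and a mean of 3.81 (at most 8) in the permutations. Of the 23 and 30 lower probe sets, 6 were the same, against 0.55 for independent lists, while the permutations gave a mean of 4.58 and up to 11. The permutations did not hold the numbers of higher or lower probe sets fixed, so their overlaps are not at equal list sizes. Over the 85 probe sets higher in Nup2-MN, the median H2b-MN difference was 0.51, and 72 of them (84.7%) were above 0 in H2b-MN, against a mean of 49.4% and at most 67.4% in the permutations. The 23 probe sets lower in Nup2-MN were all below 0 in H2b-MN, with a median of -0.82. The permutations gave a mean of 67.2% and up to 87.5% below 0, with medians down to -0.52.

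**Figure D2:**
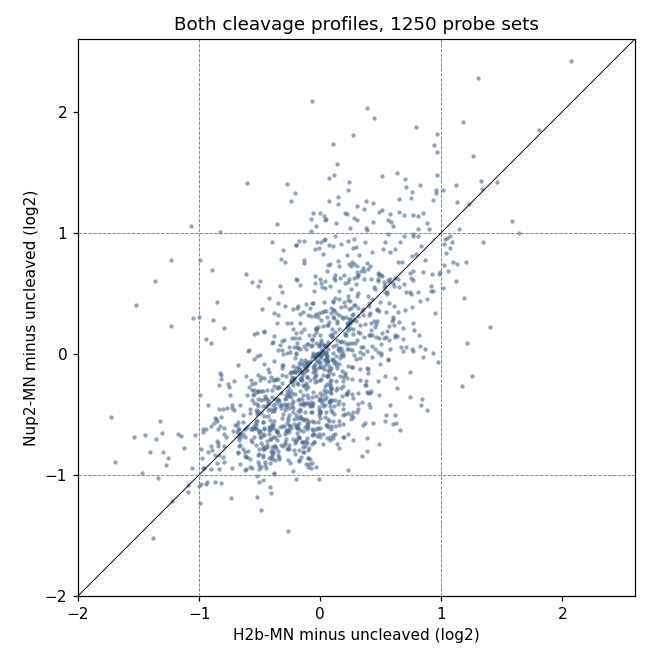
Nup2-MN minus uncleaved against H2b-MN minus uncleaved, both in log2, with 1 point for each of the 1250 probe sets; the solid line marks equal differences and dashed lines mark 2-fold. The differences correlate (r = 0.598) but scatter around the line, with more points beyond 2-fold higher in Nup2-MN (85) than in H2b-MN (35).

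The third comparison set Nup2-MN directly against H2b-MN, at the unequal cleavage times and temperatures given above. Nup2-MN was at least 2-fold higher in 54 probe sets (4.32%) and at least 2-fold lower in 23 (1.84%), with a median difference of -0.07 and an SD over probe sets of 0.516. The highest were c6Mbo0666, at 9.08 in Nup2-MN against 6.93 in H2b-MN and 7.00 in uncleaved DNA (log2 difference 2.16), and c6Mbo1185, at 8.88 against 6.76 and 7.83 (2.12). The lowest were c6Mbo0109, at 5.89 in Nup2-MN against 7.33 in H2b-MN and 6.08 in uncleaved DNA (-1.44), and c6Mbo1078, at 5.86 against 7.29 and 6.12 (-1.43). In the 54 probe sets higher in Nup2-MN, the median was 1.03 for Nup2-MN minus uncleaved and -0.22 for H2b-MN minus uncleaved. Of these, 29 were also at least 2-fold higher in Nup2-MN than in uncleaved DNA, and 8 were at least 2-fold lower in H2b-MN than in uncleaved DNA. In the 23 lower ones the medians were -0.55 and 0.62. Of the 77 probe sets past the threshold, 70.1% were higher, against 74.6% (53 higher, 18 lower) with quantile normalization of the 3 columns and 84.9% (79 higher, 14 lower) after each column was centred on its median, which moved the median difference from -0.07 to 0.10. At 1.5-fold without centring, 136 were higher and 145 lower.

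The direct difference ran in groups of neighbouring probe sets in both directions. Members of a run were not shown to be separate sites, since shuffled orders remove likeness from any source. Runs of 3 or more neighbours at least 0.5 apart numbered 22 where Nup2-MN was higher, against a mean of 2.4 and at most 10 in shuffled orders, and 22 where it was lower, against a mean of 3.9 and at most 11. Nup2-MN exceeded H2b-MN by at least 0.5 on the log2 scale in each of the 12 probe sets 1174 to 1185 (mean 1.28) and in each of the 10 probe sets 1025 to 1034 (mean 1.11), while the longest such run in 1000 shuffled orders was 7. In 1174 to 1185, Nup2-MN lay above uncleaved DNA by a mean of 0.82 and H2b-MN below it by a mean of -0.46. In 1025 to 1034 these means were 0.55 and -0.56. The next longest run, 662 to 668, had a mean of 1.19 and matched the longest run of the shuffles. In the other direction the longest run was 7 probe sets, 857 to 863 (mean -0.63), against 8 in shuffled orders. Averaged over windows of 50 probe sets, Nup2-MN minus H2b-MN was highest in 1151 to 1200 (0.47, SD 0.62 over the 50 probe sets) and 651 to 700 (0.45, SD 0.63), and lowest in 251 to 300 (-0.38, SD 0.41). In shuffled orders no window mean rose above 0.25 or fell below -0.29.

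Neighbouring probe sets were more alike in the Nup2-MN profile than in the H2b-MN profile. For Nup2-MN minus uncleaved, the correlation between a probe set and the next was 0.615 (95% block bootstrap interval 0.567 to 0.653). It was 0.393 at a distance of 2 and 0.243 at a distance of 3. For H2b-MN minus uncleaved it was 0.332 (0.268 to 0.388), then 0.097 and -0.016. The difference between the profiles at a distance of 1 was 0.283 (0.225 to 0.338). Nup2-MN minus H2b-MN kept a correlation of 0.260 (0.137 to 0.358) at a distance of 5. Shuffling the order of the probe sets 1000 times gave no correlation between neighbours beyond 0.115 in either direction in any of these 3 profiles. The signal itself was also alike between neighbours, at 0.324 in uncleaved DNA, 0.307 in H2b-MN and 0.397 in Nup2-MN at a distance of 1. Shuffling removes likeness from any source, so exceeding it does not tie the likeness to cleavage. Runs of 3 or more neighbours at least 0.5 higher in Nup2-MN than in uncleaved DNA numbered 33, against a mean of 7.0 and at most 15 in shuffled orders. For H2b-MN they numbered 10, against a mean of 2.6 and at most 12. Runs of 3 or more neighbours at least 0.5 lower numbered 51 for Nup2-MN, against a mean of 19.7 and at most 30 in shuffled orders, and 22 for H2b-MN, against a mean of 3.7 and at most 10. The longest single runs did not separate the profiles in the same way. For Nup2-MN minus uncleaved they held 8 probe sets higher and 10 lower, against up to 10 and 11 in shuffled orders. For H2b-MN minus uncleaved they held 8 higher and 6 lower, against up to 6 and 7. The longest higher runs, 1205 to 1212 for Nup2-MN and 1208 to 1215 for H2b-MN, lay in the last stretch of probe sets described below. Outside that stretch the longest higher runs held 5 for Nup2-MN (422 to 426) and 4 for H2b-MN (453 to 456), neither longer than in shuffled orders.

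**Figure D3:**
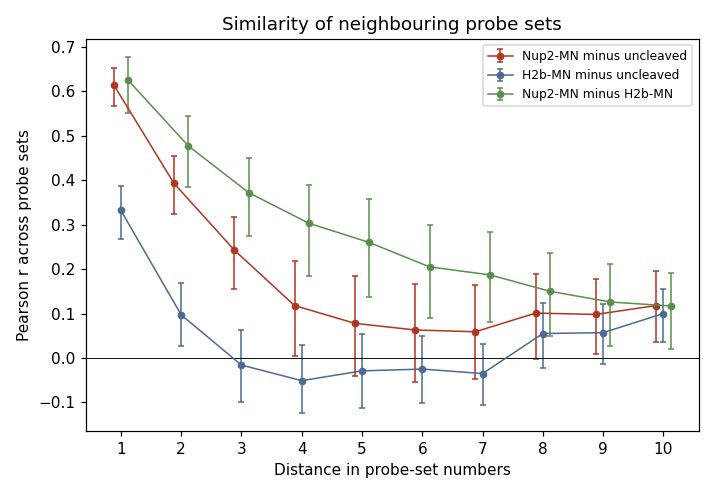
Pearson correlation across probe sets between values 1 to 10 probe-set numbers apart, for the 3 log2 differences, with 95% block bootstrap intervals as bars and points shifted sideways for clarity. At a distance of 1 the value is 0.615 for Nup2-MN minus uncleaved and 0.332 for H2b-MN minus uncleaved, and Nup2-MN minus H2b-MN falls off most slowly, to 0.260 at a distance of 5.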

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

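The test of opposite directions below was chosen after the values were seen. Probe set c6Mbo1185 was the 1 probe set of 1250 that was at least 2-fold higher in Nup2-MN than in uncleaved DNA (log2 difference 1.06) and at least 2-fold lower in H2b-MN (-1.07), so that the cleaved samples differed by 2.12. With 1 value per group, this difference was not tested. It is the last member of the run 1174 to 1185, in which Nup2-MN exceeded H2b-MN by a mean of 1.28.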

How the results depend on the processing

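Without the spread between the 3 experiments, the counts below describe differences past a threshold and are not calls set against error. For Nup2-MN minus uncleaved (85 higher, 23 lower), the lower count was 8 with columns centred on their medians, 13 with quantile normalization and 10 with the trend with level removed. The higher and lower counts were 212 and 287 at a 1.5-fold threshold, and 37 and 8 after averaging 3 neighbours. For H2b-MN minus uncleaved (35 and 30) they were 133 and 134 at 1.5-fold, and 4 and 8 after averaging. For Nup2-MN minus H2b-MN (54 and 23), the lower count was 14 with centring and 15 with the trend removed. The counts were 136 and 145 at 1.5-fold, and 29 and 4 after averaging. A lower threshold and averaging move counts by construction; for the others, the cause was not tested, apart from the 0.15 gap between the medians that centring removes. The excess of higher over lower probe sets in Nup2-MN, against either other sample, thus held in every setting run at 2-fold. It turned at 1.5-fold, which was run only without centring, so the turn may come from the offset between columns. The remaining 35 values of counts and correlations stayed within 1.5 times the reported count, or within 1 bootstrap SD of the correlation. Of 48 recomputed values of the named probe sets under settings that can move them, 41 stayed past the threshold and 0 changed sign. The 7 that did not all came from averaging 3 neighbours, and included the 4 named for H2b-MN minus uncleaved, such as c6Mbo0830 (from 2.07 to 0.55). Leaving out the lowest 10% of probe sets or both ends moved no count by over 1.5 times. Leaving out probe sets near the chromosome ends by coordinates, correcting for GC content, changing the promoter window and the pseudocount were not run, since positions were not at hand and the values are already log2.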

Other observations

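The tests in this part were chosen after the results were seen, except the correlations between neighbours and their values with the trend with level removed. Probe sets of low signal differed less between samples: in the 250 dimmest probe sets (mean log2 signal up to 6.20) the SD of Nup2-MN minus uncleaved was 0.39, and 4 of them were at least 2-fold higher, against an SD of 0.71 and 22 in the 250 probe sets of middle signal (7.11 to 7.90). The lowest signal was 4.64 in uncleaved DNA, 4.65 in H2b-MN and 4.64 in Nup2-MN, so dim probe sets had little room to fall. Whether they were less affected by cleavage was not tested. Probe set c6Mbo0830 had the largest rise over uncleaved DNA in both cleaved samples. It was followed by 3 probe sets, 831 to 833, that lay below uncleaved DNA in H2b-MN (mean -1.10) and above it in Nup2-MN (mean 0.50).

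Over the last 46 probe sets, 1205 to 1250, a stretch set by the best single step in the mean of both profiles, both cleaved samples lay above uncleaved DNA. Nup2-MN was higher by 0.68 ± 0.51 (SD over probe sets; 44 of 46 above 0) and H2b-MN by 0.45 ± 0.43 (39 of 46). The stretch was chosen for being high in both, so its size is no separate evidence. A bias of the values with signal level is argued against as the cause by the probe sets outside the stretch: their trend with level gives a shift of -0.118 at the levels of the stretch (95% block bootstrap interval -0.167 to -0.069), the opposite direction. A lower signal of the uncleaved sample there, for example from its DNA or its arrays, may account for a step shared by both comparisons. It cancels out of Nup2-MN minus H2b-MN, so alone it would leave that difference as it is elsewhere. The difference was 0.23 ± 0.44 over the stretch and -0.04 ± 0.52 elsewhere. In 1218 to 1247, 30 of the 46 probe sets, it was 0.05 ± 0.26. There Nup2-MN lay above uncleaved DNA by a mean of 0.51 and H2b-MN by 0.46. That part was picked as the longest under 2-fold between the cleaved samples, so its likeness is no separate evidence. Of 10000 lists of probe sets elsewhere with the same levels, 20.27% varied as little in this difference. Of the other stretches of 46 neighbours, 51.68% did. This spread cannot decide the question, since the uncleaved signal does not enter the difference. The explanation by a lower uncleaved signal stays open. Cleavage by both fusions over the stretch remains open as well. The smaller of the 2 mean differences (0.450, H2b-MN) is above 0, but the direction in which cleavage moves the signal was not given in the sources used here. With 1 uncleaved column, cleavage and a lower uncleaved signal cannot be told apart.

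The greater likeness of neighbours in the Nup2-MN profile (0.615 against 0.332) was weighed against 2 technical explanations. Independent noise on single probe sets, if larger in the H2b-MN sample, would lower the correlations at all distances by the same factor. The ratio of the correlation at distance 2 to that at distance 1 was 0.639 in Nup2-MN and 0.293 in H2b-MN. The difference of 0.346 (95% block bootstrap interval 0.198 to 0.530) argues against such noise as the whole cause. Noise may still account for part of the gap, and it was not measured here. A bias with signal level is argued against too, since the difference between the profiles, 0.283, was 0.262 after the trend with level was removed, and it was 0.296 without the last 46 probe sets. Whether the fusion protein or the longer and warmer cleavage of the Nup2-MN sample accounts for the difference of 0.283 cannot be told apart, since no 2 cleaved samples share a time and temperature.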
